A study of Mus musculus with 7 samples.

How the data were processed

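RNA expression was measured on 7 single-colour Affymetrix arrays from mouse: whole testis at 4 weeks (wild type and ERM knockout), primary Sertoli cells (wild type and ERM knockout at 4 weeks, ERM knockout at 10 weeks) and the TM4 cell line without and with transfection of ERM. Each array was its own group, taken from the labels. The values deposited by the authors are probe set intensity values on a linear scale with a lowest value of exactly 1, and the software and scaling used to make them are not given in the sources used here. The testis arrays share a table of 12488 probe sets. The Sertoli and TM4 arrays share another table of 45101 probe sets and do not have a common scale, with trimmed means of 183 and 186 in TM4 and of 288 to 299 in Sertoli cells.

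Each array was scaled so that the mean of its non-control probe sets between the 2nd and 98th percentiles equalled 500. Scaled intensities below a floor of 100, which is 0.2 of that trimmed mean, were set to the floor before log2 ratios were taken. A ratio with 1 array below the floor is a bound, and no ratio was given with both below it. Probe sets annotated to exactly 1 gene were kept, 10833 for 8251 genes in testis and 34945 for 18161 genes in the other table. Those naming several genes (396 and 932), no gene (1193 and 9160) or controls (66 and 64) were left out of gene counts. Gene identifiers of 10817 and 34741 of the kept probe sets matched a gene table of assembly GRCm38.p6, which was used for names only and changed no symbol. No coordinates were used, since the files name no genome build. A gene was represented by the probe set with the highest mean scaled intensity over all arrays of its table.

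The comparisons were testis knockout against wild type, Sertoli knockout against wild type at 4 weeks, TM4 with against without ERM, Sertoli knockout at 10 against 4 weeks, and, as an addition to these 4, Sertoli knockout at 10 weeks against wild type at 4 weeks. Genes were counted when they differed at least 2-fold. With 1 array per group no statistical test across samples was possible. Fixed gene lists, 12 for cell types and 11 for processes, were described by the median log2 ratio of their members. The percentile of the median came from 10000 random lists of the same size matched on mean signal in 20 bins, and it describes these arrays and not the animals. Agreement between comparisons was given as correlations across genes and as shared genes, with 100 simulations of unchanged arrays where a wild-type array was shared. Comparing Sertoli cells with testis was planned but not made, because they were measured on different array designs.

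The lists, the thresholds, the naming rule and 7 alternative settings were chosen before the data were examined. The rule named Etv5, then in each of the 4 main comparisons the 10 genes highest and the 10 lowest among those with the brighter array at 500 or above and all detected probe sets in the same direction. It also named up to 4 members of each list by size of ratio, and Cxcl12, Cxcl5, Ccl7 and Mmp12 in any case. Genes with only clone or provisional names were counted but not named. The alternatives were the values as deposited, ratios centred on 0, quantile normalization, a floor at 0.1 or 0.4 of the trimmed mean, the mean over probe sets, and leaving out probe sets prone to cross-hybridisation. Counting only genes with at least 2 probe sets in the same direction was added after seeing the data.

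The steps were tested on simulated data with the noise of each main comparison. A true log2 change of 1.5 was called in 95.0% of 100 genes for testis, 91.0% for Sertoli cells at 4 weeks, 100% for TM4 and 91.0% for the knockout ages. Changes were placed only in genes that read at least 4 times the trimmed mean on the second array. The rates of called changes therefore do not hold for dimmer genes. Unchanged genes were called in 0.0414%, 0.281%, 0% and 1.53%. Of 100 unchanged lists of 20 genes, 5%, 2%, 6% and 4% were set apart. Those lists held genes drawn at random with independent noise. Their rates therefore do not hold for the fixed lists, whose members may vary together. The simulated noise was set from the robust spread of gene log2 ratios between the arrays compared. That spread mixes measurement noise with any difference between the animals or preparations of the pair. The rates therefore do not show how further animals or preparations would vary. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.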

Results

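Gene expression was measured on 7 Affymetrix arrays hybridised with RNA from mouse testis, from primary Sertoli cells and from the TM4 cell line. Sertoli cells are the somatic cells of the seminiferous tubule that nurse the germ cells, and TM4 is a line derived from mouse Sertoli cells. ERM, encoded by Etv5, is a transcription factor of the ETS family that is expressed in Sertoli cells and in germ cells. Whole testis of wild-type and ERM knockout mice was compared at 4 weeks. Sertoli cells were compared between wild type and ERM knockout at 4 weeks, and a knockout preparation was also taken at 10 weeks. TM4 cells were studied with and without transfection of ERM. The title of the study names the loss of germline stem cells in mice without ERM as its subject. On the deposited scale, median intensity ranged from 87.9 to 134 over the Sertoli and TM4 arrays and was 304 on both testis arrays. The share of probe sets at or above the floor ranged from 72.0% to 77.0% on the former and was 82.2% and 82.1% on the latter. Each of the 7 groups was represented by 1 array, so there were no replicates and no difference had a replicate check. No p-value or standard deviation across samples could be given, and the number of arrays limits the precision of every value. The only error estimate came from bright genes with more than 1 probe set on the same pair of arrays. It gave a standard deviation per probe set, in log2 units, of 0.30 in testis, 0.26 in Sertoli cells at 4 weeks, 0.19 in TM4 and 0.30 between the knockout ages. That spread reflects probe sets within an array pair and not animals or cultures.

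Etv5 was examined first, because its level bears on the labels. In Sertoli cells, probe set 1428142_at gave a scaled intensity of 710 on the wild-type array, 910 on the array labelled ERM knockout at 4 weeks and 995 on the array labelled knockout at 10 weeks. The knockout to wild-type ratio at 4 weeks was 1.28 for this probe set, 1.13 for 1450082_s_at and 1.05 for 1420998_at. None of the 3 Etv5 probe sets was therefore lower on an array labelled knockout. The part of the gene removed in the mutant is not given in the sources used here, and a probe set outside that part would check nothing, so these values do not settle the labels. In TM4 cells the ratio of transfected to untransfected was 1.17, 1.51 and 1.13 for 1428142_at, 1450082_s_at and 1420998_at. The array labelled knockout at 10 weeks gave larger ratios to wild type, of 1.40, 1.56 and 1.23 for the same probe sets. The TM4 ratios therefore do not show how far the transfection raised ERM. No probe set of the testis array was named Etv5. Directions below are those between arrays as labelled.

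**Figure D1:**
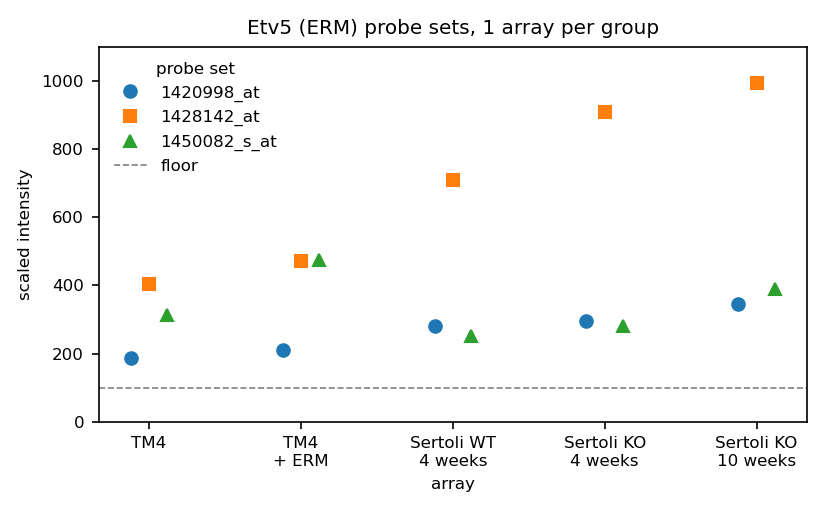
Scaled intensity (linear axis from 0) of the 3 Etv5 probe sets on the 5 arrays of Sertoli and TM4 cells, with 1 point per probe set and array and the floor of 100 as a dashed line. On the arrays labelled knockout, 1428142_at lay at 910 and 995, above the 710 of the wild-type Sertoli array.

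In whole testis at 4 weeks, the lists of cell cycle, differentiating spermatogonia and meiotic genes had lower medians on the array labelled ERM knockout, and those of Sertoli and Leydig cells higher medians with no member past 2-fold. Hells, a chromatin remodelling helicase, was 5.01-fold lower (93228_at, 115 against 574). Dazl, an RNA-binding protein of germ cells, was 3.39-fold lower, with log2 ratios of -1.76 and -1.75 on its 2 probe sets. Stra8, which acts at the entry into meiosis, was at least 2.86-fold lower, since its signal of 286 in wild type lay below the floor on the other array. Kitl and Inhbb, growth factors made by Sertoli cells, had log2 ratios of 0.97 each.

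Of 7516 genes at or above the floor, 40 were at least 2-fold higher and 64 at least 2-fold lower on the testis array labelled knockout. Restricting these to genes with at least 2 probe sets in the same direction left 9 higher and 5 lower. With the floor at 0.1 of the trimmed mean 61 were higher, and with the floor at 0.4 22 were higher and 35 lower. Among bright genes the other large decreases were Gml (2.87-fold), the Polycomb ring finger gene Pcgf5 (2.82-fold), the splicing regulator Ptbp2 (2.44-fold), the BMP antagonist Nog (2.32-fold), the nuclear pore gene Nup54 (2.31-fold), the linker histone H1f10 (2.29-fold), Lsm3 (2.26-fold) and the chromatin protein Hmgb2 (2.25-fold). On the higher side stood Tnni3 (2.69-fold), Cited2 (2.34-fold), Serpina5 (2.32-fold), the cholesterol exporter Abca1 (2.32-fold, with a log2 ratio of 0.22 on its other probe set), Rab31 (2.31-fold), the gap junction gene Gja1 (2.28-fold), Rasd1 (2.27-fold), the carbonic anhydrase Car2 (2.26-fold) and the splicing regulator Mbnl1 (2.25-fold). Kif5a headed the list at 14.9-fold or more, but only through probe set 98827_i_at (16.4 against 1487), while its other probe set had a log2 ratio of 0.07. The other probe set of Gja1 had a log2 ratio of 0.54 and that of Ptbp2 of -0.62, both within 2-fold.

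Gene lists fixed before the data were examined were described by the median log2 ratio of their members, and a list was called set apart when its median lay outside the central 95% of 10000 random lists of like brightness. Lists set apart numbered 8 of 23 in testis, 14 of 23 in Sertoli cells at 4 weeks, 2 of 22 in TM4 and 11 of 23 between the knockout ages. Differentiating spermatogonia genes had a median of -0.37 in the testis (percentile 0.18), with 2 of 8 members at least 2-fold lower. These were Stra8 and Crabp1, a retinoic acid binding protein that was at least 2.22-fold lower. Dmrt1 (-0.58) and Uchl1 (-0.44) were also lower. Meiotic spermatocyte genes had a median of -0.17 (percentile 0.92), with Dazl the 1 member of 15 past 2-fold. Sycp1, of the synaptonemal complex, had a log2 ratio of -0.87, while Pgk2 stood at 0.58. This call was lost with the floor at 0.4 of the trimmed mean. Cell cycle genes had a median of -0.33 (percentile 0), led by Mcm2 (at least 2.20-fold lower), Top2a (-1.09), Mki67 (-0.91) and Cdc20 (-0.69).

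Undifferentiated spermatogonia and stem cell genes were not set apart in the testis (median -0.05, percentile 37.7), and none of 11 members was past 2-fold. Of the 24 genes in that list 15 had a probe set, and Gfra1 and Epcam lay below the floor on both arrays. The list therefore cannot say whether stem cells were spared. Among them Mcam had a log2 ratio of -0.29, Id4 of -0.24, Cdh1 of 0.21 and Neurog3 of 0.19. Sertoli cell genes had a median of 0.26 (percentile 99.9) over 18 members, all within 2-fold, with Inha at 0.79 and Wt1 at 0.75. Of these members 14 lay above 0 and 4 below, among the latter Amh (541 against 877 in wild type) and Gdnf (432 against 529). Leydig cell genes had a median of 0.28 (99.5). The steroid enzyme Hsd3b6 was at 0.72 and Insl3, a hormone of mature Leydig cells, at -0.62. Macrophage genes had a median of 0.20 (98.5), with Aif1 at 0.88 and Cd68 at 0.74, a call lost with the floor at 0.4 of the trimmed mean. Glycolysis genes (median 0.34, percentile 99.7), led by Hk2 at 0.73, and junction genes (0.21, percentile 99.2), led by Gja1 at 1.19 and F11r at 0.84, were set apart as higher. Spermatid genes (0.18, percentile 95.6), fibroblast genes (0.16, percentile 97.2) and chemokines (0.07, percentile 85.1) were not. Within these lists Tssk1 was at 0.74, Dcn at 1.03 and Ccl12 at 0.40, and Pdgfra had log2 ratios of 1.18 and -0.05 on its 2 probe sets. Cxcl12 had testis log2 ratios of 0.16 and 0.74 on 2 probe sets and of at least 0.64 on another. Ccl7 and Mmp12 were at -0.18 each, and Cxcl5 lay below the floor on both testis arrays. The remaining 11 lists had medians from -0.14 for red blood cell genes to 0.18 for housekeeping genes, and none was set apart. The Gapdh 3' to 5' ratio, a sign of RNA integrity, was 1.08 in wild type and 1.11 on the other array.

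In primary Sertoli cells at 4 weeks, chemokines were lower as a list on the array labelled ERM knockout, with 13 of 26 at least 2-fold lower. Ccl7, which attracts monocytes, was 24.7-fold lower (1421228_at, 111 against 2739). Cxcl5, a neutrophil chemokine, was 9.22-fold lower at 893 against 8235. Mmp12, the macrophage elastase, was 12.7-fold lower. For Cxcl12, a chemokine that guides stem cells to their niche, the brightest probe set was at least 12.6-fold lower, a further probe set had a log2 ratio of -3.32 and the remaining probe set went the other way at 0.37. These 4 genes were named from knowledge of the study, so their direction is not independent evidence. Cxcl12, Cxcl5 and Ccl7 also belong to the chemokine list and are among its 13 lower members. The list is therefore not wholly independent of that knowledge either.

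Altogether 108 genes were at least 2-fold higher and 504 at least 2-fold lower of 15842 at or above the floor in the 4-week Sertoli comparison. With at least 2 probe sets in the same direction the counts were 25 and 162. Large decreases included Serpinb2 (13.6-fold), an inhibitor of plasminogen activators, Cxcl3 (13.1-fold), Mndal (10.8-fold, on a probe set that can cross-hybridise), Ms4a4d (at least 8.83-fold), the leukocyte tetraspanin Cd53 (8.29-fold), the lysosomal protease Ctss (8.12-fold) and the fungal glucan receptor Clec7a (7.81-fold). The largest increases rested on 1 probe set each. Vil1, a cytoskeletal protein of microvilli, went from 141 to 18037 (128-fold), Sox1 from 1.67 to 5941, Nop14 from 1.67 to 1359 and Slc9a4 from 8.36 to 708. Nop14 read 1029 on the 10-week knockout array and 1514 and 1324 on the TM4 arrays without and with ERM. For Nop14 the low wild-type reading therefore stood out, and its ratio does not show an increase in knockout. Wnt4, a signalling gene of the gonad, was 4.32-fold higher with log2 ratios of 2.11 and 1.20 on 2 probe sets. Nat8f5 (4.18-fold), Spatc1l (4.06-fold), Muc5ac (3.70-fold), Tmem114 (3.14-fold) and the lipoprotein receptor Lsr (3.03-fold) followed.

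Chemokines as a list had a median of -1.08 in this comparison (percentile 0), with 13 of 26 members at least 2-fold lower and none at least 2-fold higher. Ccl2 had a log2 ratio of -2.96. Macrophage markers moved the same way, with a median of -0.90 (percentile 0) and 5 of 13 at least 2-fold lower. Among these, besides Ctss, were Lyz2 (-1.81), Fcer1g (-1.59) and Cd68 (-1.51), and the other 8 members were within 2-fold. Interferon response genes had a median of -0.56 (percentile 0), led by Ifit2 (-2.09), Rsad2 (-1.52) and Oas1a (-0.94). FGF and ERK pathway response genes, several of them feedback inhibitors, had a median of -0.40 (percentile 0.04), led by Spred1 (-1.26), Phlda1 (-1.24) and Spry2 (-1.23). On the array labelled knockout at 10 weeks, against the same wild-type array, this list was set apart as higher instead (0.22, percentile 98.5). That call was kept under 6 of 7 alternatives. Cell cycle genes had a median of -0.75 (percentile 0), with 6 of 25 at least 2-fold lower, among them Mcm2 (-1.39), Mcm5 (-1.29) and Birc5 (-1.13). Fibroblast and collagen genes had a median of -0.47 (percentile 0.09), led by Col3a1 (-1.41, with -0.10 on another probe set), a call lost when log2 ratios were averaged over probe sets. Matrix proteases and inhibitors as a list were not set apart (-0.11, percentile 16.0). Besides Mmp12, Mmp13 was at least 3.56-fold lower in that list, and Mmp11 was at 0.98.

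Germ cell genes were also detected on the Sertoli arrays, and their lists differed in direction. Meiotic spermatocyte genes had a median of -0.51 (percentile 0) over 32 members, with Tex15 (-1.23), Adam2 (-0.90), Tdrd1 (-0.79) and Sycp2 (-0.79) lowest. Differentiating spermatogonia genes had a median of -0.49 (percentile 0.04), with Esx1 (-1.81), Stra8 (-1.74) and Dmrt1 (-1.11) past 2-fold. Spermatid genes were set apart as higher (0.14, percentile 98.2), with the protamine gene Prm2 at 1.04 and Smcp at 0.82. Of the 29 members 17 lay above 0 and 12 below, and only 1 was past 2-fold. Pdha2 was among those below, at 825 against 1375 in wild type. Undifferentiated spermatogonia genes were not set apart (-0.12, percentile 17.5), with Id4 at 0.70 and Mcam at least 1.58-fold lower. Of the 22 genes of that list with a probe set, 18 reached the floor on at least 1 TM4 array. Gfra1 read 1128 on the untransfected TM4 array and 169 in wild-type Sertoli cells, while Id4 went the other way, at 75.4 and 2838. On these arrays the list therefore cannot say whether stem cells were spared.

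Sertoli cell genes themselves had a median of 0.26 (percentile 99.97), with the actin bundler Espn at 1.19, Gdnf at 1.02 and Gata4 at 0.93. Gdnf is the growth factor on which spermatogonial stem cells depend. It was not higher elsewhere, reading 432 on the knockout and 529 on the wild-type testis array. In TM4 it read 502 with and 525 without ERM. Niche growth factors as a list were not set apart (-0.06, percentile 35.3), with Cxcl12 and Gdnf at opposite ends. Leydig cell genes had a median of 0.46 (percentile 99.97), led by the steroid enzyme Cyp17a1 at 1.64, although Hsd11b1 was at -1.06. Junction genes had a median of 0.23 (percentile 99.1), with Jam2 at 0.74 and Cgn at 0.72, a call lost when probe sets were averaged. Acute stress genes had a median of -0.19 (percentile 2.28), with Hspa1b at -1.18, but this call was lost under 3 of 7 alternatives. Peritubular (-0.16), endothelial (-0.05), red blood cell (0.03), epididymal (0.06), cholesterol synthesis (-0.01) and glycolysis (0.06) lists were not set apart. Housekeeping genes had a median of -0.26 (percentile 0.01), and Actb had log2 ratios of -1.27 and -0.37 on its 2 probe sets. The array labelled knockout at 4 weeks also carried high 18S ribosomal RNA control signals. The 5' probe set read 4551, against 349 on the wild-type array and 352 on the array labelled knockout at 10 weeks. Gapdh 3' to 5' ratios were 0.777 and 0.829 on the wild-type and the 4-week knockout array.

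**Figure D2:**
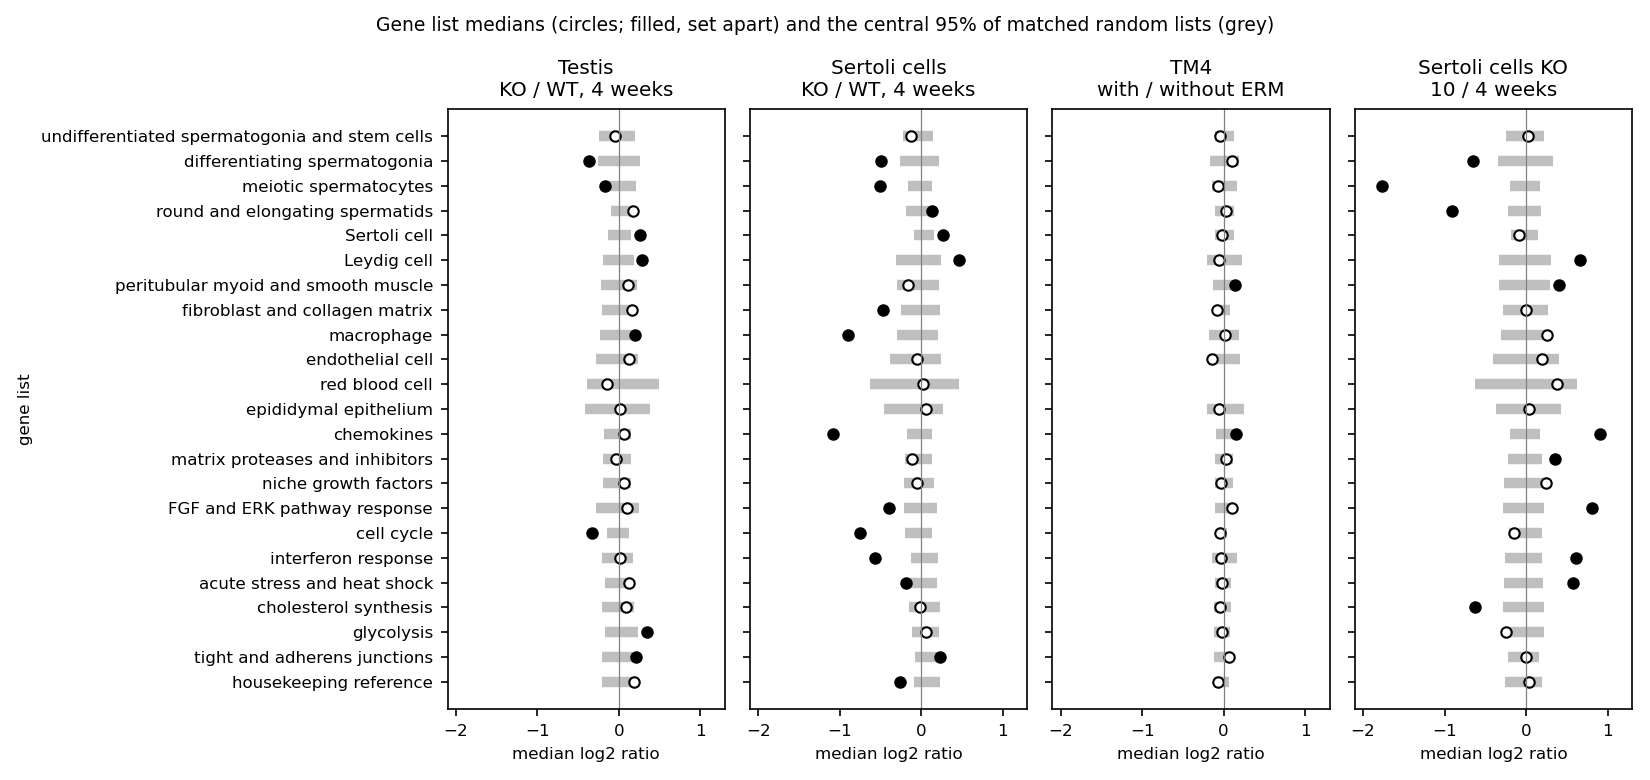
Median log2 ratio (x axis) of each of the 23 gene lists (y axis) in the 4 main comparisons, as circles that are filled where the list was set apart, over grey bars that span the central 95% of matched random lists. The chemokine list lies at -1.08 in Sertoli cells at 4 weeks, 0.15 in TM4 cells and 0.90 between the arrays labelled knockout at 10 and 4 weeks.

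In TM4 cells the pair of arrays had a correlation of 0.985 across probe sets, and the chemokine list had a slightly higher median on the array labelled as transfected with ERM. That median was 0.15 (percentile 99.5) over 28 members, of which 1 was at least 2-fold higher and 27 were within 2-fold. Of these members 18 had a log2 ratio above 0 and 10 below. Cxcl11 was 3.44-fold higher on 1 probe set (386 against 112) and below the floor on both arrays on its other probe set. Cxcl12 was 1.70-fold higher on its brightest probe set (log2 ratios of 0.77, 0.63 and -0.01), Cxcl10 1.41-fold and Ccl7 1.38-fold higher. Cxcl5 stood at 0.37, whereas Cxcl13 was at -0.49, with 0.12 on its other probe set. Mmp12 lay below the floor on both TM4 arrays. TM4 is a limited counterpart of the primary Sertoli cells here. The untransfected TM4 and wild-type Sertoli arrays had a correlation of 0.748 across probe sets. The Sertoli cell genes Sox9 and Wt1 read 95.1 and 97.4 on the former, below the floor, and 5220 and 3802 on the latter. Inhbb went the other way, at 3833 and 318. FGF and ERK response genes were not set apart (0.10, percentile 96.3), though Spry4 was 2.47-fold higher (another probe set at a log2 ratio of 0.31) and Ier3 and Spry2 stood at 0.93 and 0.59.

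Counts in TM4 were 49 genes at least 2-fold higher and 68 at least 2-fold lower of 16136, and 9 and 8 with at least 2 probe sets in the same direction. With the floor at 0.1 of the trimmed mean they were 134 and 193, and with the floor at 0.4 they were 24 and 27. The largest ratios among the named genes, those of As3mt and Tbx22, went between below the floor and a high value on 1 probe set each. As3mt read 2762 without and 2.69 with ERM, and Tbx22 2479 and 33.2. Lower with ERM were also Omd (9.42-fold), Nptx1 (7.20-fold), C1qtnf9 (619.5 without and 59.1 with), Dkk4 (at least 5.89-fold), Efcab15 (at least 5.80-fold), Tmem26 (at least 5.29-fold), Sox1 (4.64-fold) and Ints7 (4.60-fold, with another probe set at a log2 ratio of -0.04). Higher with ERM were Kcnh5 (at least 11.7-fold), the calcium channel subunit Cacna2d2 (10.7-fold), Olfr1264 (at least 6.31-fold), Fcer1a (5.87-fold), the DNA repair helicase Ercc2 (at least 5.53-fold), Slc13a3 (3.76-fold), Zfp474 (3.59-fold), Ankrd28 (3.41-fold), Lnx2 (2.61-fold) and Uox (2.08-fold). Ercc2, Slc13a3 and Ankrd28 had another probe set with a log2 ratio of 0.13, 0.00 and 0.25. Peritubular genes were set apart as higher (0.14, percentile 97.7), with Myh11 at 0.50 and Actg2 at 0.48, but this call was lost under 5 of 7 alternatives. The medians of the other 19 lists with a median lay between -0.14 for endothelial genes and 0.10 for differentiating spermatogonia genes, and none was set apart. The red blood cell list had 2 members above the floor and no median.

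Between the arrays labelled ERM knockout at 10 and at 4 weeks, the lists of meiotic and spermatid genes had lower medians in the older Sertoli cell preparation and chemokines a higher median. Meiotic spermatocyte genes had a median of -1.77 (percentile 0), with 20 of 29 at least 2-fold lower and none at least 2-fold higher. Hormad1, which marks unsynapsed chromosome axes, was 10.6-fold lower (1207 to 114), Ybx2 9.05-fold lower, and Sycp2, of the synaptonemal complex, had a log2 ratio of -3.05. Chemokines had a median of 0.90 (percentile 100), with 12 of 26 at least 2-fold higher. Ccl7 was 5.17-fold, Ccl2 4.39-fold, Cxcl5 3.04-fold and Cxcl11 5.26-fold higher at 10 weeks. Cxcl12 was at least 5.06-fold higher on its brightest probe set, with another unmoved at a log2 ratio of 0.00. The 18S 5' control read 4551 on the 4-week array and 352 on the 10-week array. Age and array differ together, and no wild-type array at 10 weeks was analysed here.

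In all, 664 genes were at least 2-fold higher and 557 at least 2-fold lower at 10 weeks of 15833, or 228 and 130 with at least 2 probe sets in the same direction. Highest were Wfdc18 (13.9-fold), the imprinted gene Peg12 (at least 12.4-fold), the matrix protein Thbs1 (8.31-fold, log2 ratios of 3.06 and 2.77 on 2 probe sets), Mndal (8.06-fold), Nxph1 (7.99-fold, with another probe set at a log2 ratio of 0.19), the prostaglandin D synthase Ptgds (7.78-fold, log2 ratios of 2.96 and 3.13), Vmn1r65 (7.76-fold), Ms4a4d (at least 7.22-fold), Reg3g (7.21-fold) and Serpinb6b (7.13-fold). Lowest were Vil1 (107-fold) and Sox1 (at least 59.4-fold), the probe sets that stood out on the 4-week array, then Tex101 (at least 11.8-fold), Cers3 (10.9-fold), Spata33 (10.0-fold), Ube2t (9.81-fold), Spata4 (9.65-fold) and Nek2 (at least 8.90-fold). Another probe set of Ube2t had a log2 ratio of -0.05, and another of Nek2 -0.15.

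Spermatid genes had a median of -0.91 between these arrays (percentile 0), with 12 of 29 at least 2-fold lower, led by Tnp2 (-3.13), and Prm2 at -2.61. Differentiating spermatogonia genes had a median of -0.65 (percentile 0.03). Sycp3, a synaptonemal complex gene that was placed in this list, was at -2.65. Undifferentiated spermatogonia genes were not set apart (0.02, percentile 60.4), although Cdh1 was at -2.99 and Id4 at -1.34. As in the 4-week comparison, that list cannot say whether stem cells were spared. The cholesterol synthesis list had a lower median (-0.62, percentile 0), with 11 of 13 members within 2-fold. The 2 past it were Fdft1 (-1.39, with another probe set at 0.23) and Sqle (-1.36). Higher lists besides chemokines were FGF and ERK response (0.81, percentile 100; Spred1 at 2.01), Leydig cell (0.66, percentile 99.98; Cyp17a1 at 1.69), interferon response (0.62, percentile 100; Ifit2 at 2.09), acute stress (0.57, percentile 100; Atf3 at 1.47), peritubular (0.40, percentile 99.5; Tpm2 at 1.19) and matrix proteases and inhibitors (0.36, percentile 99.96; Mmp23 at 1.87 and Mmp12 at 1.51). Several of these differ less when the 10-week array is set against the wild-type array of 4 weeks. There the interferon list was at 0.08 (percentile 70.2) and matrix proteases at 0.09 (percentile 90.7), neither set apart. FGF and ERK response was at 0.22 (percentile 98.5). Ifit2 read 902 in wild type, 212 on the 4-week knockout array and 901 on the 10-week array. Sertoli cell genes (-0.09, percentile 26.6), macrophage genes (0.26, percentile 96.2; Ctss at 1.97), cell cycle genes (-0.15, percentile 7.74; Cdc20 at -2.40) and niche growth factors (0.24, percentile 97.4) were not set apart. The other 7 lists had medians from -0.24 for glycolysis to 0.38 for red blood cell genes and were not set apart.

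**Figure D3:**
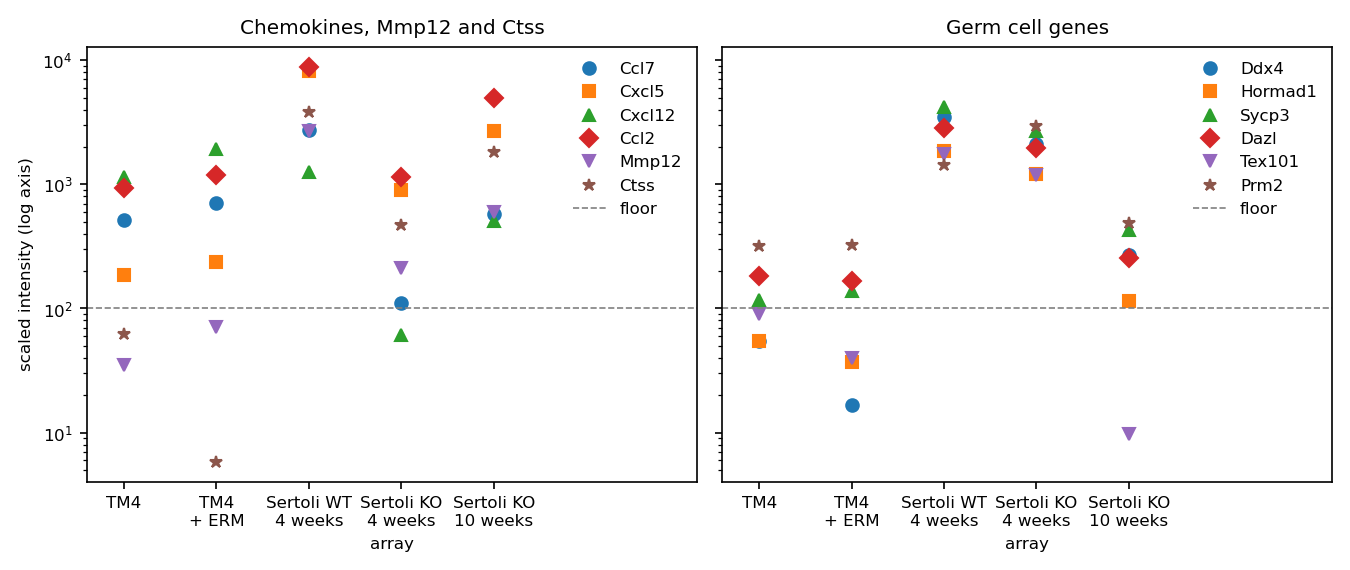
Scaled intensity (log axis) of 6 genes of the chemokine and macrophage group and of 6 germ cell genes on the 5 arrays of TM4 and Sertoli cells, 1 point per gene and array, with the floor of 100 as a dashed line. Ccl7 lies at 2739, 111 and 574 on the wild-type, 4-week knockout and 10-week knockout Sertoli arrays, and Ddx4 at 3497, 2124 and 268.

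Against the wild-type Sertoli array of 4 weeks, the array labelled knockout at 10 weeks differs in both age and genotype. Meiotic spermatocyte genes had a median of -1.94 (percentile 0), with 24 of 32 at least 2-fold lower, and Hormad1 and Ddx4 had log2 ratios of -4.03 and -3.70. Ccl7 was 4.77-fold lower, Mmp12 4.46-fold, Cxcl5 3.03-fold, and Cxcl12 2.48-fold lower on its brightest probe set, with others from -1.87 to 0.38 in log2 ratio. The chemokine list had a median of -0.21 (percentile 1.25) and was set apart under only 1 of 7 alternatives. Macrophage genes had a median of -0.43 (percentile 0.14), led by Cd68 (-1.41), and Leydig cell genes one of 0.76 (percentile 100), with Cyp17a1 10.1-fold higher. In total 258 genes were at least 2-fold higher and 672 at least 2-fold lower of 15894, or 92 and 179 with at least 2 probe sets in the same direction.

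Changes were compared between experiments across genes, which are not independent replicates. Log2 ratios of the 4-week testis and Sertoli pairs had a Pearson r of 0.10 and a Spearman rho of 0.15 over 6907 genes. Both were at least 2-fold lower for 5 genes (Dck, Hells, Mcm2, Pdpn and Stra8), where independent lists would share 2.0. Acss1 was at least 2-fold higher in both (0.29 for independent lists), and Dcn was higher in testis and lower in Sertoli cells (1.29 for independent lists). These genes were named after their values were seen. The 4-week Sertoli pair and the TM4 pair had an r of -0.09 and a rho of -0.10 over 14813 genes. Cxcl11 was the 1 gene at least 2-fold lower in the former and higher in the latter, where independent lists would share 0.93. B4galnt1 and Sox1 went the opposite way, against 0.30, and Spatc1l was higher in both, against 0.21. None of these counts was tested. Testis and TM4 had an r of 0.02 over 6959 genes. The Sertoli arrays labelled knockout at 4 and 10 weeks, each against the same wild-type array, had an r of 0.33, below the 0.50 that simulated unchanged arrays sharing a control gave. The covariance was 0.0838 against 0.0564 simulated. Both were at least 2-fold lower for 121 genes, against 21.6 for independent lists and a mean of 1.54 in the simulation, and at least 2-fold higher for 25, against 1.58 and 1.64. Both comparisons use the same wild-type array. The simulation gave every gene the same normal noise, with a standard deviation of 0.24 per array in log2 units. It held no outlying readings on the shared array. Neither the shared genes nor the covariance therefore measures an excess over a shared control.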

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

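The tests of all 3 patterns weighed here were chosen only after the results were seen. Macrophage genes went opposite ways in the 4-week comparisons, with a median log2 ratio of -0.90 in Sertoli cells and 0.20 in testis, where 0 of 15 members passed 2-fold and the list was no longer set apart with the floor at 0.4 of the trimmed mean. Dcn, a matrix proteoglycan, also did, at -1.04 in Sertoli cells (with -0.05 on its other probe set) and 1.03 in testis. Neither difference was tested. Some control probe sets outside the gene counts were high on the Sertoli array labelled knockout at 4 weeks and others low. The log2 ratios to wild type for 18S ribosomal RNA were 1.56 (3' probe set), 3.71 (5') and 3.36 (middle), and that of the 3' pyruvate carboxylase control was 1.85. The 3' controls for the transferrin receptor (447 against 617), dap (776 against 1383) and lys (226 against 390) read lower than in wild type.

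Chemokines were lower on the Sertoli array labelled knockout at 4 weeks (median -1.08), and whether the high 18S controls of that array bear on this ratio, or on the 0.90 between 10 and 4 weeks, was not tested and stays open. If fewer macrophages were carried into that preparation, chemokines and macrophage markers would be lower alike: over all measured members the medians were -1.08 and -0.90, and over 14 chemokines and 6 markers selected as bright on the wild-type array, which is also the denominator, they were -1.97 and -1.21, a difference of -0.76 with an interval of -1.78 to 0.51 that leaves it open. Ctss read 468 against 3801 and lay below the floor in TM4, where 10 of the 16 macrophage markers reached it on at least 1 array and 77.0% of all probe sets did on the untransfected array. Different inflammatory activation of the preparations may be open, with the interferon list at -0.56, which shares no gene with the chemokines, though genotype and preparation change together. On the 10-week knockout array, against the same wild-type array, the interferon list was at 0.08 (percentile 70.2) and not set apart. An effect of ERM itself may be open as well, since the TM4 chemokine median was 0.15. However, the Etv5 ratios in TM4 do not show how far the transfection raised ERM. TM4 also differed from the primary cells, with a correlation of 0.748 between the untransfected TM4 and wild-type Sertoli arrays. The chemokine list was set apart as lower on the 10-week knockout array under only 1 of 7 alternatives, and these explanations cannot be told apart.

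The lists of differentiating spermatogonia, meiotic spermatocytes and spermatids were lower on the knockout Sertoli array at 10 weeks than at 4 weeks (medians -0.65, -1.77 and -0.91), and that of undifferentiated spermatogonia was not (0.02). In TM4, 18 of the 22 measured genes of the undifferentiated list also reached the floor, so its median cannot say whether stem cells were spared. Fewer germ cells of all stages carried over may be open: stage medians of 27 genes selected on arrays outside this ratio spanned 1.61, but reshuffled lists reached 2.58 at their 95th percentile, above the size of the pattern, so the test could hardly exclude it. The 3 undifferentiated spermatogonia genes among these 27 had a median of -1.34. The levels were, at 4 and 10 weeks, 2708 and 431 for Sycp3, counted here with differentiating spermatogonia, and 2124 and 268 for Ddx4, of the meiotic list. On the untransfected TM4 array, where 77.0% of all probe sets reached the floor, Sycp3 and Ddx4 read 116 and 55.1, and 23 of the 32 meiotic genes reached it on at least 1 TM4 array. Loss of germ cells in the knockout with age cannot be told apart from normal ageing or from the cell isolation, because the 31 germ cell genes bright on either knockout array, whose median was -2.46 between the ages, were at -2.55 against wild type at 4 weeks and no wild-type array at 10 weeks was analysed here. These 31 genes were selected on the arrays that form the ratio between the ages, so its size depends on that selection.

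In the testis labelled knockout, the lists of differentiating spermatogonia and meiotic spermatocytes were lower and those of Sertoli cells, Leydig cells and macrophages higher, while undifferentiated spermatogonia were not set apart (-0.05); the meiotic and macrophage calls were lost with the floor at 0.4. The trend of all genes with brightness gives the higher lists a difference of -0.0042 from the lower lists, where 0.53 was observed (interval 0.26 to 0.77). These lists were called against random lists already matched on brightness, so that outcome was largely fixed in advance. Medians of all genes in brightness bins ran only from -0.058 to 0.046, which argues against a brightness trend as the whole cause. A lower share of differentiating and meiotic germ cells, which would raise the other types alike, may be open: the medians of 8 other lists, undifferentiated spermatogonia included, spanned 0.33, and 46.5% of 10000 reshuffles of their 102 genes spanned as much, but their 95th percentile of 0.55 exceeds the observed 0.53, so the test could hardly exclude it. With 1 array per genotype, differences between individual mice and an effect of ERM on expression within cells remain untested.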

How the results depend on the processing

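The 7 alternatives other than the restriction by probe sets were planned, and that restriction was chosen after the data were seen. Of the counts and correlations, 82 stayed within 1.5 times or within their spread and 19 moved; of the list medians 787 stayed, 1 moved and 1 reversed; of the values of named genes 474 stayed and 82 moved. With the floor at 0.1 of the trimmed mean, 61 testis genes were higher, 134 TM4 genes higher and 193 lower. With the floor at 0.4 these were 22, 24 and 27, and 35 testis genes were lower. Sertoli and TM4 log2 ratios had an r across genes of -0.062 at the low and -0.13 at the high floor; the cause was not tested. Requiring at least 2 probe sets in the same direction left, higher and lower, 9 and 5 genes in testis, 25 and 162 in Sertoli cells at 4 weeks, 9 and 8 in TM4, 228 and 130 between the knockout ages and 92 and 179 for 10-week knockout against wild type, fewer by construction. The peritubular median in TM4 turned from 0.14 to -0.0082 with the mean over probe sets, and the cause was not tested. No scaling moved the median of all genes by over 0.1. No paired analysis was possible because each group has 1 array, and Sertoli cells against testis was not run. Signal over background limits weak genes: between 72.0% and 82.2% of probe sets reached the floor.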

Other observations

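The hypotheses tested stand with the results weighed above, and none of the values here was put to a further test. Leydig cell genes were higher as a list on the Sertoli array labelled knockout at 10 weeks than on the wild-type array of 4 weeks. Their median was 0.76, with 4 of 10 at least 2-fold higher and 6 within 2-fold. Those past 2-fold included the steroid enzymes Cyp17a1 (3.33), Cyp11a1 (1.27) and the cholesterol transporter Star (1.17). The cholesterol synthesis list had a lower median (-0.64, percentile 0) with 2 of 13 at least 2-fold lower, Sqle at -1.28 and Cyp51 at -1.04. The acute stress list had a higher median (0.51, percentile 100) with 2 of 16 at least 2-fold higher, Trib3 at 1.27 and Atf3 at 1.24. Peritubular (0.34, percentile 99.6) and endothelial (0.35, percentile 99.4) lists had higher medians, with no member at least 2-fold higher. Spermatid genes (-0.60, percentile 0) had 10 of 28 and cell cycle genes (-0.63, percentile 0) 11 of 25 at least 2-fold lower. Age and genotype differ together in this pair.

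Actb differed between probe sets on the Sertoli arrays at 4 weeks. Its brightest gene probe set read 13869 on the array labelled knockout and 33542 in wild type, whereas its 3 control probe sets read 14352 to 15925 and 12966 to 14781. Sox1 read 5941 on that knockout array and 1.67 and 1.71 on the wild-type and the 10-week arrays, all from the same probe set, and it was also 4.64-fold lower with ERM in TM4. Of genes at least 2-fold different with at least 2 detected probe sets, all probe sets went the same way for 14 of 23 in testis, 187 of 265 in Sertoli cells at 4 weeks, 17 of 34 in TM4 and 358 of 493 between the knockout ages.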
